A study of Homo sapiens with 20 samples.

How the data were processed

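Expression was measured on 20 arrays: 18 Affymetrix PrimeView arrays of primary human RPE cells with a lentiviral hairpin and 2 U133 Plus 2.0 arrays of iRPE clones. RPE cells were grown in 2% serum and iRPE clones in 5%, and 100 ng of RNA per knockdown sample was labelled. The deposited values are a 1-colour signal intensity on a linear scale, which the submitters' processing notes attribute to MAS5; its version and settings, and any later scaling, are not given in the sources used here. The 2% trimmed means of the 18 arrays ran from 199 to 220, so these arrays were not scaled to a common trimmed mean, whereas that of both iRPE arrays was 500.0. All values were above 0. The number of arrays, 2 per group, limits the precision of every value.

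Values were used as deposited, as log2(value + 16), because the array medians lay within 0.236 of each other on that scale, under the limit of 0.5 set for normalizing. Of 49495 probe sets 202 controls were left out, and of the 49293 others 45278 carried 1 gene symbol, 1333 several and 2682 none, the last kinds not being used. Probe sets in the lowest 40% by mean level (under 5.99) were left out except those of the 9 factors, the 8 targets and LHX2. A gene was represented by its probe set with the highest mean, and Y-linked genes and XIST were left out, which left 12272 genes. On the iRPE arrays the same steps took 54675 probe sets, 41091 of them with 1 gene symbol, to 13908 genes.

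Groups followed the labels: shControl and 8 knockdowns. A model with 1 coefficient per group was fitted in limma 3.58.1 under R 4.3.3, with moderated two-sided tests, an intensity trend, 9 residual and 5.02 prior degrees of freedom, and a median residual SD of 0.146. Comparisons were each knockdown against shControl, the mean of the 8 against shControl, and each knockdown against the mean of the other 7. P-values were adjusted by the Benjamini-Hochberg method within a comparison, or over the 64 pairs of a targeted factor and a knockdown, and genes under 0.05 are called. Camera, with a preset correlation of 0.01, tested 18 gene lists in 8 knockdowns, adjusted over 144 tests; the shift is the mean fold change of the list minus that of the other genes. The lists overlap, and the RPE marker list holds 6 of the 9 factors, so a target counts in its own knockdown. Similarity of knockdowns was set beside 100 simulated sets of unchanged groups that share the 2 controls. Correlations over fewer than 10 samples used exact permutation and the others 100000 permutations, two-sided, in SciPy 1.17.1 with numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15; figures used matplotlib 3.10.9.

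The comparisons, lists, filters, tests and most alternatives were set before the data were examined, and so was the rule for genes to name. For each knockdown these are the 8 largest rises and 8 largest falls among called genes whose arrays both lie outside the control range, and up to 4 members of each list by p. For the mean they are the 8 and 8 with all 16 arrays on 1 side, against the other knockdowns the 3 and 3 largest, and for iRPE up to 6 genes of a list by level and the 6 largest clone differences each way. The 9 factors are always named, and names of uncharacterized loci were passed over. The 22 and 2 genes called in all 8 knockdowns are named in part and were chosen after their values were seen.

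Alternatives were quantile normalization, log2(value + 1), no filter on level, no intensity trend, the mean over probe sets of a gene, a fit of the 4 arrays of a comparison alone, an estimated correlation in camera, the array number as a block, and leaving out each array. After seeing the data fry, covariates for the interferon mean and for the ACTB 3 prime to 5 prime difference, the lists against the other 7 knockdowns, the lists with these covariates, an estimated correlation in every other setting, the ratio of counts with each array left out, the size and SE of changes with the covariates, and changes of the factors relative to spike-in RNA were added. The fit was tested on simulated data with known changes in shPAX6. It recovered 21 of 67 genes changed by 0.5 on the log2 scale (31.3%), 63 of 67 at 1 (94.0%) and 65 of 66 at 2 (98.5%), with 5 false calls among 154, and 0 limma calls in an unchanged knockdown. A list of 43 genes shifted by -0.5 was found, and 0 of 143 other list tests was called. The simulated noise was independent between genes and equal in all groups. In the data the estimated correlation within a list reached 0.777, so this check does not cover the list calls.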

Results

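Primary human retinal pigment epithelium (RPE) cells, the pigmented layer that nourishes photoreceptors and clears their shed membranes, were transduced with lentiviral short hairpins. The hairpins targeted 8 transcription factors (PAX6, OTX2, MITF, SIX3, FOXD1, GLIS3, SOX9 or ZNF92), or were a control hairpin (shControl). Cells were selected with 1 µg/ml puromycin from 24 hours on and harvested on day 5. Each of the 9 groups was profiled on 2 expression arrays, 18 in all. Per the labels the 2 arrays of a factor are lines with different hairpins, so their spread holds hairpin differences too, while no label says what separates the 2 control arrays. On 2 further arrays of another design were clones 42 and 46 of RPE-like cells made from fibroblasts (iRPE). A test covered 12272 genes, and with 2 arrays per group their number limits the precision. P-values measure only the spread between these samples, which may be technical, because nothing says that the 2 control arrays came from separate cultures. All values are log2 of signal plus 16, folds are of signal plus 16, and ± gives the SD over 2 arrays or, after a fold change, the SE.

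The first comparison asked whether each hairpin lowered its own target, and in all 8 knockdowns the target fell. OTX2, a homeobox factor of eye and forebrain fate, fell by 2.42 ± 0.33, from 11.21 ± 0.14 to 8.79 ± 0.49 (adjusted p = 7.55e-05), leaving 18.1% of the control signal once the added 16 is taken off. PAX6, the paired-box factor needed for eye formation, went from 8.39 ± 0.13 to 6.56 ± 0.10 (-1.83 ± 0.17, adjusted p = 1.66e-06, 24.5% left). MITF, which switches on pigment genes, went from 10.17 ± 0.28 to 8.46 ± 0.02 (-1.71 ± 0.25, adjusted p = 0.000151, 29.6% left). SIX3, a homeobox factor of the anterior neural plate, went from 9.97 ± 0.39 to 8.06 ± 0.63 (-1.91 ± 0.29, adjusted p = 0.000160, 25.4% left). The forkhead factor FOXD1 went from 9.59 ± 0.08 to 7.99 ± 0.87 (-1.60 ± 0.26, adjusted p = 0.000267, 31.5% left). SOX9, an HMG-box factor, went from 10.35 ± 0.05 to 9.08 ± 0.29 (-1.27 ± 0.16, adjusted p = 5.32e-05, 40.7% left). The zinc-finger factors changed least in test terms, ZNF92 from 9.56 ± 0.58 to 8.09 ± 0.81 (-1.47 ± 0.32, adjusted p = 0.00368, 34.6% left) and GLIS3 from 7.99 ± 0.14 to 7.25 ± 0.40 (-0.74 ± 0.22, adjusted p = 0.0275, 57.3% left). These adjusted p-values cover the 64 pairs of a targeted factor and a knockdown. Relative to spike-in RNA, a comparison chosen after seeing the data, the changes of MITF (-0.92), SIX3 (-0.97), SOX9 (-0.63), GLIS3 (-0.32) and ZNF92 (-0.94) were smaller by over 1.5 times, and those of PAX6 (-1.62), OTX2 (-2.03) and FOXD1 (-1.44) were not.

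The 2 arrays of each target lay below all arrays of the other groups, and each hairpin alone lay below the control mean: -1.76 and -1.90 for PAX6, -2.77 and -2.08 for OTX2, -1.70 and -1.72 for MITF, and -2.36 and -1.46 for SIX3. The remaining differences were -2.22 and -0.98 for FOXD1, -1.02 and -0.46 for GLIS3, -1.06 and -1.48 for SOX9, and -0.90 and -2.05 for ZNF92. FOXD1 thus came to -0.98 without shFOXD1 replicate 1. The ZNF92 call ended without shControl replicate 2 (-1.06, adjusted p = 0.0923) or shZNF92 replicate 2 (-0.90, adjusted p = 0.0587). The GLIS3 call ended without shControl replicate 2 (-0.64, adjusted p = 0.213) or shGLIS3 replicate 1 (-0.46, adjusted p = 0.203), and with the mean over probe sets (-0.34, adjusted p = 0.149). Other GLIS3 probe sets differed by -0.11, -0.29, 0.09 and -0.65, other SOX9 probe sets by -0.99 and -0.13, and other PAX6 probe sets by -0.58 and -1.18. The other probe set of OTX2 differed by -2.52 and that of MITF by -1.53.

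**Figure D1:**
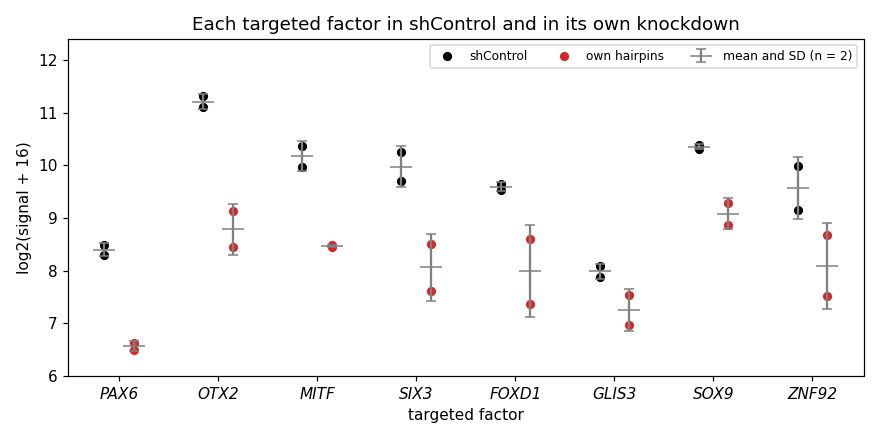
Level (log2 of signal plus 16) of each targeted factor in the 2 shControl arrays (black) and in the 2 arrays of its own knockdown (red), with grey lines for the mean and SD (n = 2). In every factor both red points lie below both black points.

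The targeted factors were also read in each other's knockdowns, to see which of them fell with which. MITF fell in 4 other knockdowns: shOTX2 (-1.17 ± 0.25, adjusted p = 0.00360), shPAX6 (-0.97 ± 0.25, adjusted p = 0.0128), shSIX3 (-0.91 ± 0.25, adjusted p = 0.0177) and shSOX9 (-0.82 ± 0.25, adjusted p = 0.0289). OTX2 fell in shPAX6 (-1.18 ± 0.33, adjusted p = 0.0177). By array, MITF lay at -1.66 and -0.68 in shOTX2, -0.87 and -1.08 in shPAX6, -1.20 and -0.62 in shSIX3 and -0.87 and -0.77 in shSOX9. OTX2 lay at -1.61 and -0.74 in shPAX6. The falls of MITF in shOTX2 and shSIX3 and of OTX2 in shPAX6 thus differed between the 2 hairpins. Relative to spike-in RNA, a comparison chosen after seeing the data, MITF lay at -0.78 in shOTX2, -0.76 in shPAX6, 0.03 in shSIX3 and -0.18 in shSOX9, and OTX2 at -0.97 in shPAX6, so for shSIX3 and shSOX9 the fall of MITF rests on the scaling. Those were the 5 calls among 56 pairs of a factor and another factor's knockdown, where 18 had an unadjusted p under 0.05. OTX2 (-0.94) and SIX3 (-0.84) in shSOX9 and MITF (-0.73) in shGLIS3 missed the threshold (adjusted p = 0.0504), as did MITF in shZNF92 (-0.71) and SIX3 in shPAX6 (-0.82, adjusted p = 0.0507). Differences spanned -1.18 to -0.27 for OTX2, -1.17 to -0.40 for MITF and -0.84 to -0.55 for SIX3 over the 7 other knockdowns. They spanned 0.08 to 0.41 for PAX6, -0.12 to 0.06 for FOXD1, -0.02 to 0.12 for SOX9, -0.17 to 0.49 for GLIS3 and -0.52 to -0.09 for ZNF92. Adjusted over all genes, OTX2 (adjusted p = 0.0455) and SIX3 (0.0432) in shSOX9 and SIX3 in shPAX6 (0.0372) were called, and MITF in shSIX3 was not (0.0665). LHX2, an eye-field factor that no hairpin targeted, lay -0.46 to -0.14 from shControl over the 8 knockdowns and was called in shSOX9 (-0.46 ± 0.15, adjusted p = 0.0336 over all genes; 0.18 relative to spike-in RNA). The 5 calls became 0 without shControl replicate 2 and 12 without shControl replicate 1. They became 14 and 13 without either shOTX2 array, 13 and 15 without either shSIX3 array, and 11 with no filter on level.

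Against shControl, the mean of the 8 knockdowns asks what changed on average over the hairpins against a factor, and the largest rises were in interferon-induced genes. A gene that changed in only some knockdowns can be called here too. IFI27, a mitochondrial interferon-response protein, rose by 4.40 ± 0.62 (adjusted p = 0.000594). MX1, a GTPase that blocks virus replication, rose by 4.35 ± 0.69 (adjusted p = 0.00102), and OAS1, a sensor of double-stranded RNA, by 4.15 ± 0.53 (adjusted p = 0.000506). The tether of budding virus BST2 (4.17), the antiviral enzyme RSAD2 (4.06), the ubiquitin-like ISG15 (3.84), the RNA-binding IFIT1 (3.81) and OAS3 (3.80) complete the 8 largest. The largest falls were in pigment genes: TYRP1, a melanin-synthesis enzyme (-2.85 ± 0.42, adjusted p = 0.000728), PMEL, the fibril protein of the melanosome (-2.59 ± 0.38, adjusted p = 0.000728), and TYR, the rate-limiting enzyme of melanin (-2.39 ± 0.41, adjusted p = 0.00137). The secreted protein NELL2 (-2.36), the poly(A) polymerase TENT5C (-2.22), the RNA-binding NANOS1 (-2.19 ± 0.26, adjusted p = 0.000470), the thyroxine carrier TTR (-1.88 ± 0.24, adjusted p = 0.000506) and elastin (ELN, -1.85) fell too. In all, 1920 genes were higher and 1311 lower, and 1491 and 1549 after quantile normalization. With values as deposited, 1015 of the higher and 868 of the lower genes had all 16 knockdown arrays outside the control range on that side. With the ACTB 3 prime to 5 prime difference of each array, a sign of RNA quality, as a covariate chosen after seeing the data, limma called 341 genes in the mean. It then called 1674 in shPAX6, 794 in shMITF, 632 in shOTX2, 2 in shSOX9 and 0 in shSIX3, shFOXD1, shGLIS3 and shZNF92, where 1934, 828, 1211 and 1439 had an unadjusted p under 0.05. In the 3231 genes called in the mean the median change in their direction went from 0.47 to 0.45 and its median SE from 0.12 to 0.18, so calls ended because the covariate, which differs between groups, widened the SE. With the interferon mean as a covariate, also chosen after seeing the data, it called 0 in the mean and in each knockdown, with 777 in the mean and 265 to 2033 in the knockdowns at an unadjusted p under 0.05. There the median change went from 0.47 to 0.31 and the SE from 0.12 to 0.27, and in the genes called in shFOXD1 and shGLIS3 the median change went from 1.89 to 0.25 and from 1.90 to 0.35. Many genes called in shFOXD1 and shGLIS3 belong to the interferon list whose mean is the covariate. Their change shrinks by construction, so nothing is read from that drop. Called genes numbered 2089 without shControl replicate 1 and 124 without shControl replicate 2, where 6 of the 8 falls lost their calls (TYRP1, PMEL, TYR, NELL2, TENT5C and ELN, adjusted p = 0.0617 to 0.0877).

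The 2 control arrays differed from each other in these same genes. IFI27 was at 11.01 and 6.87 in shControl replicates 1 and 2 against 12.49 to 13.79 in the 16 knockdown arrays, MX1 at 10.61 and 5.94 against 11.68 to 13.03, and ISG15 at 11.39 and 7.39 against 12.21 to 13.63. In shControl replicate 2 MX1, OAS1 (4.90), RSAD2 (5.15) and OAS3 (5.97) lay under the level cutoff of 5.99. The size of their rises thus depends on the background and the added 16. TYRP1 was at 8.89 and 10.18 against 5.14 to 8.04, PMEL at 10.29 and 11.32 against 6.60 to 9.56, and TTR at 7.41 and 8.72 against 5.82 to 6.97. For both gene groups replicate 1 lay between replicate 2 and the knockdowns. The IFI27 rise was 2.32 without shControl replicate 2 (adjusted p = 0.00770) and 6.47 without shControl replicate 1. Over the 42 interferon genes the median SD between the controls was 1.25 against a pooled 0.391 within knockdowns, whereas over all genes tested it was 0.0969 against 0.146. The test assumes the same spread in every group, so its p-values for interferon genes take the controls to be steadier than they were. All 16 knockdown arrays lay above both controls for 41 of the 42 interferon genes and below both for 21 of the 38 RPE markers. Over all 12272 genes 1121 lay above and 1028 below in every knockdown array. For 18 independent arrays chance gives 0.654% each way. The arrays come as 9 groups of 2, so that share is too low and no excess is read from it.

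**Figure D2:**
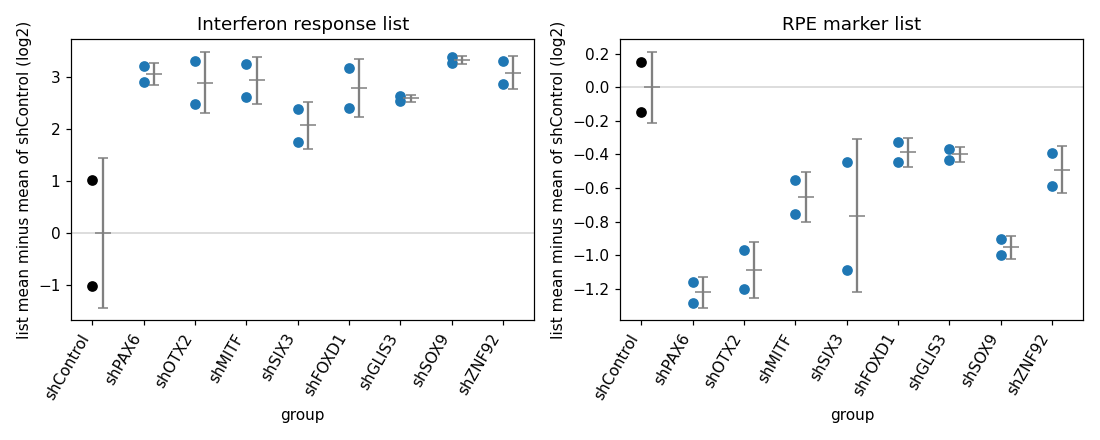
Mean of the interferon list (left) and of the RPE marker list (right) in each of the 18 arrays, minus the mean of the 2 shControl arrays (log2), with points for arrays and grey lines for the mean and SD (n = 2). The interferon mean is 1.02 and -1.02 in the controls and 1.75 to 3.38 in the knockdowns, and the RPE marker mean is -0.15 and 0.15 in the controls and -1.29 to -0.33 in the knockdowns.

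Interferon-response genes as a list moved further than other genes in each knockdown. The shift of the 42 genes against all others ran from 2.07 in shSIX3 to 3.23 in shSOX9 (lowest camera adjusted p = 1.89e-61, highest 1.16e-15; adjusted p = 0.294 to 0.328 with an estimated correlation). Without shControl replicate 2 it ran from 1.08 to 2.23 (adjusted p = 0.305 with an estimated correlation) and without shControl replicate 1 from 3.06 to 4.22 (0.292). Single genes called higher numbered 42 in shPAX6, shOTX2, shMITF, shSOX9 and shZNF92, 28 in shFOXD1, 18 in shGLIS3 and 11 in shSIX3. Adjusted over the list alone, 42 were higher in each knockdown but shSIX3 (38) and shGLIS3 (41). In all 8 knockdowns 22 genes were called higher, 8 of them of this list, including the virus-RNA sensors IFIH1 and RIGI and the regulator IRF7. Outside the list these 22 included TAP1 and HLA-B, of antigen presentation, and the transcription cofactor SP100. The list was fixed at 44 genes, so absence from it does not make a gene unrelated to interferon. Called lower in all 8 were the splicing protein SNRPN and the cold-inducible RNA-binding protein CIRBP, which had mean changes of -0.79 and -1.18. Calls in all 8 depend on the settings, as limma called 0 genes in shGLIS3 without the intensity trend. They, and the single-gene counts of shSIX3, shFOXD1 and shGLIS3, also depend on shControl replicate 2.

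RPE marker genes were the list with the strongest downward shift in 7 of the 8 knockdowns, all but shMITF, where melanin genes shifted by -0.75 and RPE markers by -0.72. Their shift ran from -1.32 in shPAX6 to -0.40 in shFOXD1 (camera adjusted p = 1.96e-13 to 4.41e-06; adjusted p = 0.294 to 0.354 with an estimated correlation). Without shControl replicate 2 it was -0.22 in shFOXD1 and -0.27 in shGLIS3 (0.603 and 0.474 with an estimated correlation), and without shSIX3 replicate 1 -0.47 in shSIX3 (0.207). Of 38 markers, 28 were lower in shPAX6 and shSOX9, 24 in shOTX2, 13 in shMITF, 10 in shSIX3, 1 in shFOXD1 and shZNF92 and 0 in shGLIS3. The marker counts in shMITF and shSIX3 depend on shControl replicate 2. The limma count of 0 stood beside 2052 genes with an unadjusted p under 0.05 over all genes in shGLIS3. Adjusted over the list alone the markers lower numbered 30, 29, 26, 19, 21, 1, 13 and 1 in that order. The 26 melanin and melanosome genes shifted by -0.81 in shPAX6 to -0.37 in shFOXD1 and shGLIS3 (camera adjusted p = 5.36e-07 to 0.0119; adjusted p = 0.294 to 0.376 with an estimated correlation). From 0 (shFOXD1, shGLIS3) to 12 (shPAX6, shOTX2) of them fell and, adjusted over the list alone, 1 to 14. The list also held rises, 6 in shPAX6, 4 in shSOX9 and 3 in shOTX2, among them the melanosome adaptor MLPH in shSOX9 (1.31 ± 0.22, adjusted p = 0.00149). Genes for phagocytosis of outer segments and lysosomes shifted by -0.52 to -0.14 (32 genes, camera adjusted p = 1.89e-05 to 0.0306; adjusted p = 0.294 to 0.367 with an estimated correlation). Of these 15 fell in shPAX6, 14 in shOTX2, 12 in shSOX9, 8 in shMITF, 2 in shSIX3 and shZNF92 and 0 in the rest (16, 14, 13, 12, 10, 3 and at most 1 adjusted over the list alone). In shFOXD1 the call ended after quantile normalization (adjusted p = 0.111) and without shControl replicate 1 (0.0526), shControl replicate 2 (0.0530) or shFOXD1 replicate 2 (0.0920), and in shGLIS3 after quantile normalization (0.116). With covariates the shFOXD1 calls of RPE markers (interferon mean) and of phagocytosis genes (either) ended, as did those of phagocytosis genes in shGLIS3 and shZNF92 with the interferon mean.

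Inflammatory and p53-target genes moved up beside the interferon genes. The 29 inflammatory and NF-kB genes shifted by 0.57 in shFOXD1 to 1.504 in shOTX2 (camera adjusted p = 2.24e-11 to 5.22e-08; adjusted p = 0.294 with an estimated correlation). Between 0 in shFOXD1, where limma gave 1287 genes of all at an unadjusted p under 0.05, and 23 in shOTX2 rose (3 and 26 adjusted over the list alone). The 26 p53 targets shifted by 0.31 in shFOXD1 to 0.99 in shPAX6 (camera adjusted p = 2.35e-09 to 5.50e-05; adjusted p = 0.294 to 0.367 with an estimated correlation). Of them 21 rose in shPAX6 and 0 in shFOXD1 (21 and 4 adjusted over the list alone). Without shSIX3 replicate 1 the shifts in shSIX3 were 0.45 for inflammatory genes and 0.35 for p53 targets (0.273 and 0.234 with an estimated correlation). With the interferon mean as a covariate the p53 call ended in shFOXD1 (adjusted p = 0.0675). The death receptor FAS and the adhesion molecule ICAM1 rose in 7 knockdowns each, and the cell-cycle inhibitor CDKN1A and the stress factor ATF3 in 6 each. These tallies depend on shControl replicate 2.

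Cholesterol and fatty-acid synthesis and cell-cycle genes shifted down in fewer knockdowns. The 26 lipid genes were called in 7, from -0.91 in shPAX6 to -0.30 in shGLIS3, and not in shFOXD1 (-0.13, adjusted p = 0.0786); the lowest adjusted p was 5.20e-11 (0.294 to 0.709 with an estimated correlation). Fallers numbered 17 in shPAX6, 16 in shOTX2, 14 in shSOX9 and 3 in shMITF (18, 17, 16 and 3 adjusted over the list alone, where shSIX3 had 13). In shSIX3 the shift was -0.19 without shSIX3 replicate 1 and -0.73 without replicate 2 (0.240 and 0.172 with an estimated correlation), and with the ACTB covariate the shZNF92 call ended (0.0870). The 43 cell-cycle genes were called in 6, from -0.77 in shPAX6 (adjusted p = 4.05e-12; 0.328 with an estimated correlation) to -0.16 in shGLIS3 (0.719 with an estimated correlation), and not in shFOXD1 (-0.05, adjusted p = 0.420) or shZNF92 (-0.04, adjusted p = 0.657). With an estimated correlation adjusted p was 0.376 in shSOX9, 0.472 in shOTX2 and 0.716 in shMITF and shSIX3. Single fallers were 32 in shPAX6, 13 in shSOX9, 12 in shOTX2 and 1 in shMITF and shSIX3 (34, 14, 12, 1 and 1 adjusted over the list alone). Without shControl replicate 1 the calls ended in shMITF (adjusted p = 0.433), shSIX3 (0.484) and shGLIS3 (0.619). Without shMITF replicate 1 the shMITF call ended (0.0611), and without shSIX3 replicate 1 the shSIX3 list was called the other way (0.09, adjusted p = 0.0451; 0.724 with an estimated correlation). Without shControl replicate 2 the list was also called down in shFOXD1 (-0.16, adjusted p = 0.00107; 0.659 with an estimated correlation) and shZNF92 (-0.14, adjusted p = 0.0152; 0.762). With the ACTB covariate the calls in shMITF, shSIX3 and shGLIS3 ended (adjusted p = 0.0711 to 0.280), and with the interferon mean as a covariate the list was called down in all 8 (0.344 with an estimated correlation).

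Lists of cell identity, stress and signalling were called in 2 knockdowns, in 1 or in none. Epithelial genes (27) shifted down in shPAX6 (-0.28, adjusted p = 0.0162; 0.335 with an estimated correlation) and shOTX2 (-0.23, adjusted p = 0.0306; 0.376 with an estimated correlation). The shPAX6 call ended without shControl replicate 2 (0.0530) or shPAX6 replicate 2 (0.0589), and that of shOTX2 without shControl replicate 2 (0.103), without shOTX2 replicate 2 (0.0540) and after quantile normalization (0.0555). Fibroblast genes (12) shifted down in shPAX6 (-0.63, adjusted p = 0.0109; 0.331 with an estimated correlation). Mesenchymal genes (35) shifted up in shMITF (0.41, adjusted p = 2.88e-05; 0.328 with an estimated correlation), a call lost without shMITF replicate 1 (0.10, adjusted p = 0.403), while the shift was 0.73 without shMITF replicate 2. With the ACTB covariate mesenchymal genes were called up in 7 knockdowns, all but shPAX6 (0.34 to 0.60), and with the interferon mean as a covariate in 5 (0.229 and 0.344 to 0.638 with an estimated correlation). The shPAX6 call of fibroblast genes ended with either covariate (adjusted p = 0.233 and 0.122), the epithelial call in shOTX2 with either (0.0921 and 0.369) and that in shPAX6 with the interferon mean (0.230). Fibroblast genes were instead called up in shFOXD1 with the ACTB covariate (0.30, adjusted p = 0.00264; 0.229 with an estimated correlation) and with the interferon mean (0.13, adjusted p = 0.0490; 0.522). Melanocyte and neural-crest genes (7) shifted down in shMITF (-0.35, adjusted p = 0.0291; 0.294 with an estimated correlation), a call lost without shControl replicate 1 (adjusted p = 0.103). Endoplasmic-reticulum and integrated-stress genes (38) shifted up in shPAX6 (0.49, adjusted p = 0.0306; 0.543 with an estimated correlation) and shSOX9 (0.39, adjusted p = 0.0375; 0.556 with an estimated correlation). Both calls ended without shControl replicate 1 (0.370 and 0.619), and that of shSOX9 also without shSOX9 replicate 2 (0.101) and with the mean over probe sets (0.0634). Both also ended with the ACTB covariate (0.124 and 0.282), which left 1 call, down in shFOXD1 (-0.30), while with the interferon mean as a covariate the list was called up in 7 knockdowns (0.398 and 0.344 to 0.549 with an estimated correlation). Without shControl replicate 2 this list was also called up in shOTX2 (adjusted p = 0.000151), shMITF (2.15e-05), shSIX3 (0.00694), shGLIS3 (0.0139) and shZNF92 (0.00322), and without shControl replicate 1 it was called down in shFOXD1 (0.000268) and shGLIS3 (0.0306). With an estimated correlation these were 0.306, 0.305, 0.455, 0.464, 0.409, 0.309 and 0.493.

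No call came from camera for visual-cycle genes (11 genes, adjusted p = 0.151 to 0.973), photoreceptor and neural-retina genes (9 genes, 0.0608 to 0.496) or endothelial and immune genes (8 genes, 0.190 to 0.860). The same held for complement genes (11 genes, 0.386 to 0.973) and Wnt, BMP and TGF-beta targets (24 genes, 0.0847 to 0.958). With the ACTB covariate photoreceptor genes were called down in shPAX6, shOTX2, shSIX3 and shSOX9 (-0.40 to -0.21) and Wnt, BMP and TGF-beta targets up in shFOXD1 (0.24), at 0.229 with an estimated correlation. Over all 18 lists and 8 knockdowns, 68 of 144 tests were called, 27 up and 41 down. With an estimated correlation camera called 0, the lowest adjusted p being 0.294, with 19 at an unadjusted p under 0.05, and 0 in every other setting, with 13 to 39. The rotation test fry, chosen after seeing the data, called 48 in 1 direction. Mean, median and test differed in sign for visual-cycle genes in shMITF, shFOXD1, shGLIS3, shSOX9 and shZNF92 (median up, test down), mesenchymal genes in shSOX9 (mean up, test down), cell-cycle genes in shZNF92 (mean and median up, test down) and melanocyte genes in shGLIS3, shSOX9 and shZNF92 (median up, test down). Complement genes in shPAX6, shOTX2, shSOX9 and shZNF92 and Wnt, BMP and TGF-beta targets in shGLIS3 and shZNF92 had a positive mean and a downward test. Complement genes in shFOXD1 had a negative median and an upward test, endothelial genes in shPAX6 a positive mean and a negative median, and fibroblast genes in shFOXD1 a positive mean and a negative median. Epithelial genes in shMITF and shGLIS3 and stress genes in shGLIS3 had a positive mean and a shift of -0.01.

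**Figure D3:**
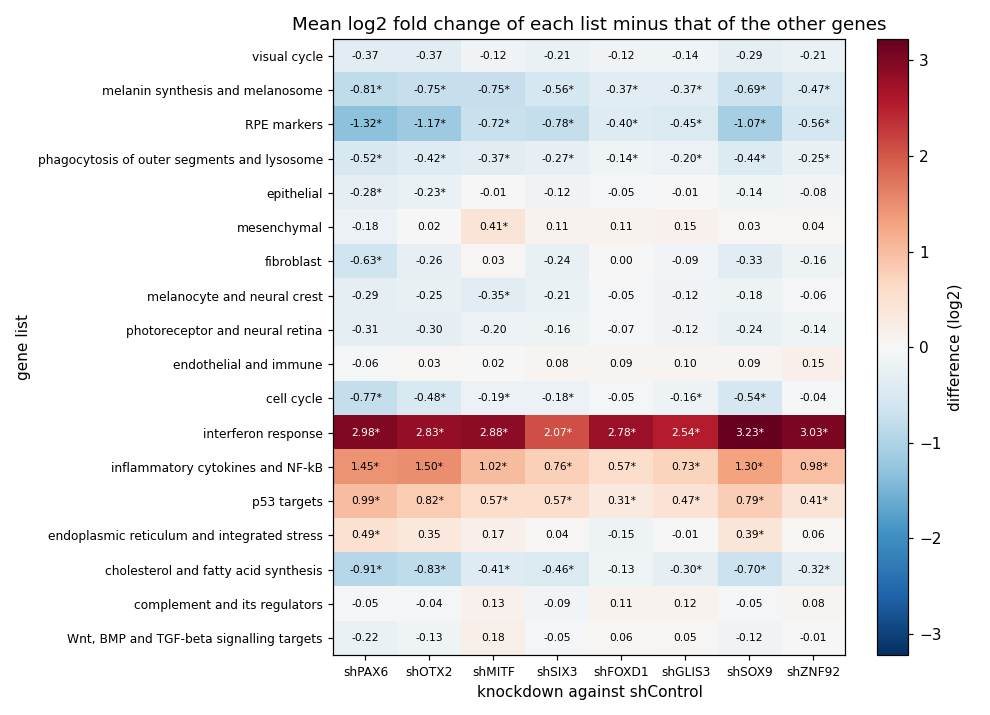
Shift of each of the 18 gene lists against all other genes (log2, colour and number) in the 8 knockdowns against shControl; * stands for a camera adjusted p under 0.05 with the preset correlation. The interferon row is the highest, 2.07 to 3.23, and the RPE marker row runs from -1.32 to -0.40.

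Knockdown of PAX6 changed the most genes against shControl. The melanin enzymes TYRP1 (-4.31 ± 0.56, from 9.54 ± 0.91 to 5.22 ± 0.11, adjusted p = 0.000216) and TYR (-4.13 ± 0.54, adjusted p = 0.000227), the melanosome protein PMEL (-4.17 ± 0.51, adjusted p = 0.000187) and elastin (ELN, -3.49 ± 0.37, adjusted p = 0.000157) fell, as did NELL2 (-4.21), the serpin SERPINE3 (-3.88), TENT5C (-3.29) and the calmodulin-binding PCP4 (-3.14). The shPAX6 level of TYRP1 lay under the level cutoff of 5.99, so the size of its fall depends on the background and the added 16. Rises were led by interferon genes, IFI27 (4.59 ± 0.82, adjusted p = 0.000880), MX1 (4.50), RSAD2 (4.39), OAS1 (4.38), the ISG15 ligase HERC5 (4.37), BST2 (4.17), the pro-apoptotic XAF1 (4.05) and IFIT1 (3.94). The NF-kB inhibitor TNFAIP3 (3.04), FAS (2.15), the p53-induced phosphatase PPM1D (1.54) and the stress factors ATF3 (3.17) and SESN2 (2.26) rose. Fallers also included the melanosome transporter SLC45A2 (-1.70), the phagocytosis ligand PROS1 (-1.76), the desaturase SCD (-1.87), the spindle gene ASPM (-1.45), the replication helicase subunits MCM2 (-0.64) and MCM7 (-0.66), and the fibroblast receptor PDGFRB (-1.39). Of 4967 called genes 3093 were higher and 1874 lower, or 2392 and 2404 after quantile normalization, and 1024 changed over 2-fold. The count was 2847 without shControl replicate 2 and 1674 with the ACTB covariate, and the 16 largest rises and falls were called in each of the 4 omissions.

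Knockdown of OTX2 gave a similar set at the top. NELL2 (-3.93 ± 0.49, adjusted p = 0.000475), TYRP1 (-3.83 ± 0.56, adjusted p = 0.000690), TYR (-3.66), PMEL (-3.60), SERPINE3 (-3.47), TENT5C (-3.40) and ELN (-3.298) fell, and so did the cardiac actin gene ACTC1 (-2.92 ± 0.47, from 11.09 ± 0.02 to 8.17 ± 0.30, adjusted p = 0.000941). IFI27 (4.37 ± 0.82, adjusted p = 0.00209), HERC5 (4.27), MX1 (4.23), OAS1 (4.07), RSAD2 (3.99), OAS3 (3.89), BST2 (3.89) and the mitochondrial nucleotide kinase CMPK2 (3.74) rose. Among RPE markers the Wnt inhibitor SFRP5 (-2.76), the signalling ligand BMP4 (-1.74) and the collagen COL8A2 (-1.42) fell. The transcription factors SNAI2 (1.94), ZEB2 (1.19) and TWIST1 (0.98) of the mesenchymal list rose, but over that list 7 genes rose and 3 fell and it was not called (shift 0.02, adjusted p = 0.929). The stress factor DDIT3 (1.90) rose, and the epithelial keratin KRT19 (-0.84) and the polarity gene LLGL2 (-0.999) fell. Of 3553 called genes 2144 were higher and 1409 lower, or 1657 and 1816 after quantile normalization, and 726 changed over 2-fold. The count was 1212 without shControl replicate 2, 2082 without shOTX2 replicate 2 and 632 with the ACTB covariate, and the 16 largest rises and falls were called in each omission.

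Knockdown of SOX9 raised HERC5 (4.89 ± 0.65, adjusted p = 0.000687), RSAD2 (4.88), OAS1 (4.71), IFI27 (4.70), BST2 (4.62), MX1 (4.60), the RNA-binding IFIT2 (4.28) and OAS3 (4.11), with the chemokine CXCL10 (3.92). TYRP1 (-3.39 ± 0.56, adjusted p = 0.00142), PMEL (-2.98), TYR (-2.93), NELL2 (-2.93), SERPINE3 (-2.79), TENT5C (-2.56), NANOS1 (-2.46 ± 0.35, adjusted p = 0.000904) and the chemokine CXCL14 (-2.32) fell. ATF3 (2.98), DDIT3 (2.07) and ATF6 (1.41), of the unfolded-protein response, and SNAI2 (1.93) rose, while PROS1 (-1.67), the lysosomal cholesterol exporter NPC1 (-0.97) and TTR (-2.10) fell. Of 3548 called genes 2286 were higher and 1262 lower, or 1626 and 1622 after quantile normalization, and 630 changed over 2-fold. The count was 2 with the ACTB covariate, where 2330 genes had an unadjusted p under 0.05. The median change of the 3548 genes went from 0.61 to 0.56 and its median SE from 0.15 to 0.24, so the calls ended mainly through the wider SE. The count was 846 without shControl replicate 2, 2122 without shSOX9 replicate 1 and 1652 without shSOX9 replicate 2, and of the 16 largest changes SERPINE3 lost its call without shControl replicate 2 (adjusted p = 0.0564).

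Knockdown of MITF lowered pigment genes, but TYRP1, PMEL and TYR also fell in the mean of the 8 knockdowns, and further in shPAX6. Against the other 7 knockdowns limma called 0 genes in shMITF, with 1035 at an unadjusted p under 0.05. The falls listed here are thus not shown to be specific to the loss of MITF. PMEL (-3.11 ± 0.51, adjusted p = 0.00483), TYRP1 (-2.91 ± 0.56, adjusted p = 0.00871), TYR (-2.26 ± 0.54, adjusted p = 0.0212), SLC45A2 (-1.34) and the melanocyte channel TRPM1 (-1.46) fell, with NANOS1 (-2.41), SERPINE3 (-2.13), TENT5C (-2.13), STRIP2 (-1.96) and NCCRP1 (-1.89). The matrix protein fibronectin (FN1, 1.59), smooth-muscle actin (ACTA2, 1.07) and the activin subunit INHBA (0.99) rose, and the melanocyte receptor EDNRB (-0.72) and the protease CAPN3 (-1.02) fell. Spike-in RNA lay -0.79 from shControl in shMITF, so falls near that size rest on the scaling as deposited. BST2 (4.66 ± 0.81, adjusted p = 0.00555), IFI27 (4.57), MX1 (4.43), OAS1 (4.19), RSAD2 (4.01), ISG15 (3.96), OAS3 (3.89) and IFIT1 (3.77) rose. Of 1135 called genes 685 were higher and 450 lower, or 523 and 595 after quantile normalization, and 303 changed over 2-fold. The count was 16 without shControl replicate 2, 420 without shMITF replicate 1 and 478 without shMITF replicate 2. Of the genes named here SLC45A2, IFI27 and OAS3 were called in every omission. Without shControl replicate 2 the others but MX1 lost their calls (adjusted p = 0.0517 for BST2 to 0.323 for SERPINE3), as did MITF itself over all genes (-1.51, adjusted p = 0.0638). Of the 16 largest changes 6 lost their calls without shMITF replicate 1 (0.0520 to 0.146) and 5, MX1 among them (0.0625), without shMITF replicate 2.

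Knockdown of SIX3 lowered TYRP1 (-3.16 ± 0.56, to 6.38 ± 1.46, adjusted p = 0.0366), PMEL (-2.59), SERPINE3 (-2.38), TYR (-2.25 ± 0.54, adjusted p = 0.0487), ELN (-2.17), TENT5C (-2.13), NELL2 (-2.08) and NANOS1 (-2.02 ± 0.35, adjusted p = 0.0357). It raised IFI27 (3.74 ± 0.82, adjusted p = 0.0441), OAS1 (3.24), IFI6 (3.14), OAS3 (3.07), the RNA sensors RIGI (2.46) and IFIH1 (2.44), HERC6 (2.43) and the ISG15-conjugating UBE2L6 (2.30). FAS (1.07) and CDKN1A (1.06) rose, and COL8A2 (-1.003) and PROS1 (-1.08) fell. Spike-in RNA lay -0.94 from shControl in shSIX3, so falls near that size rest on the scaling as deposited. Of 252 called genes 91 were higher and 161 lower, or 111 and 126 after quantile normalization, and 110 changed over 2-fold. The count was 0 in limma without shControl replicate 2 or shSIX3 replicate 1, 384 without shControl replicate 1 and 1470 without shSIX3 replicate 2, and with all arrays 2663 genes had an unadjusted p under 0.05. The count was 0 as well without any 1 array of shGLIS3, shSOX9 or shZNF92, and 137 to 140 without 1 of shPAX6, shMITF or shFOXD1. Every one of the 16 largest changes lost its call without shControl replicate 2 (adjusted p up to 0.529) or shSIX3 replicate 1 (up to 0.563), and 4 did without shSIX3 replicate 2. TYR and NELL2 did without shControl replicate 1 (0.0538 and 0.0541) and after quantile normalization (0.0576 and 0.0563), and TENT5C with log2(value + 1) (0.0509).

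Knockdown of FOXD1 had its largest rises in interferon genes, and 28 of its 66 called genes belonged to the interferon list. IFI27 (4.32 ± 0.82, adjusted p = 0.0333), BST2 (4.22), OAS1 (4.08 ± 0.71, adjusted p = 0.0271), RSAD2 (4.01), ISG15 (3.93), OAS3 (3.81), OAS2 (3.74) and HERC5 (3.50) rose. TTR (-1.71 ± 0.32, adjusted p = 0.0320), FOXD1 itself (-1.60, adjusted p = 0.0271 over all genes), the neural gene MTURN (-1.08), CIRBP (-1.03), the translation factor EIF4B (-0.99), SNRPN (-0.74), the catenin CTNND2 (-0.66) and the endosome GTPase RAB4A (-0.62) fell. Of 66 called genes 56 were higher and 10 lower, 57 changed over 2-fold, and 1287 had an unadjusted p under 0.05. The count was 0 in limma without shControl replicate 2, 106 without shControl replicate 1 and 1 without shFOXD1 replicate 2. It was 36 to 40 without an array of shPAX6, shGLIS3 or shSOX9. Every one of the 16 largest changes lost its call without shControl replicate 2 (adjusted p up to 0.759), all but FOXD1 without shFOXD1 replicate 2 (up to 0.695), 8 without shFOXD1 replicate 1 and 2 without shControl replicate 1, and EIF4B after quantile normalization (0.0709).

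Knockdown of GLIS3 raised IFI27 (4.18 ± 0.82), OAS1 (3.93 ± 0.71), RSAD2 (3.92), OAS3 (3.62), CMPK2 (3.34), OAS2 (3.16), the helicase DDX60 (3.15) and EPSTI1 (3.02), and FAS (1.19) and CDKN1A (1.18). CIRBP (-1.18 ± 0.19), SNRPN (-0.80), the mitochondrial fusion GTPase OPA1 (-0.76), RAB4A (-0.62), the aldehyde dehydrogenase ALDH2 (-0.58) and the mitochondrial carrier SLC25A5 (-0.48) fell, each at adjusted p = 0.0485. Spike-in RNA lay -0.41 from shControl in shGLIS3, so falls near that size rest on the scaling as deposited. Of 50 called genes 44 were higher and 6 lower, 44 changed over 2-fold, and 2052 had an unadjusted p under 0.05. The count was 0 in limma without shControl replicate 2 or either shGLIS3 array, 193 without shControl replicate 1 and 0 without the intensity trend. The count was 0 as well without any 1 array of shPAX6, shSOX9 or shZNF92, 22 without either shOTX2 array and 160 without either shSIX3 array. All 14 of the largest changes thus lost their calls in each of those settings that gave 0.

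Knockdown of ZNF92, a zinc-finger gene of little-known function, raised IFI27 (4.72 ± 0.82, adjusted p = 0.0111), BST2 (4.71), OAS1 (4.61 ± 0.71, adjusted p = 0.00864), MX1 (4.57), RSAD2 (4.50), ISG15 (4.11), HERC5 (4.07) and OAS2 (4.03). NANOS1 (-1.98 ± 0.35, adjusted p = 0.0116), NELL2 (-1.92 ± 0.49, adjusted p = 0.0462), TTR (-1.82), ZNF92 itself (-1.47, adjusted p = 0.0275 over all genes), the lipid phosphatase ACP6 (-1.42), the olfactory-type receptor OR51E2 (-1.42), the secreted CRISPLD1 (-1.42) and the iron-regulated ACO1 (-1.40) fell. MLPH (0.85) rose, and PROS1 (-1.11) and NPC1 (-0.67) fell. Spike-in RNA lay -0.54 from shControl in shZNF92, so falls near that size rest on the scaling as deposited. Of 459 called genes 293 were higher and 166 lower, and 180 changed over 2-fold. The count was 9 without shControl replicate 2, 240 without shZNF92 replicate 1 and 0 in limma without shZNF92 replicate 2, against 2781 with an unadjusted p under 0.05 in all arrays. It was 751 without either shSIX3 array. Without shZNF92 replicate 2 all 16 largest changes lost their calls (adjusted p up to 0.449), and without shControl replicate 2 all 8 falls and 5 of the 8 rises did (up to 0.443). Calls of 6 ended without shZNF92 replicate 1 and of 2 without shControl replicate 1, and that of NELL2 also after quantile normalization (0.0580) and with log2(value + 1) (0.0508).

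**Figure D4:**
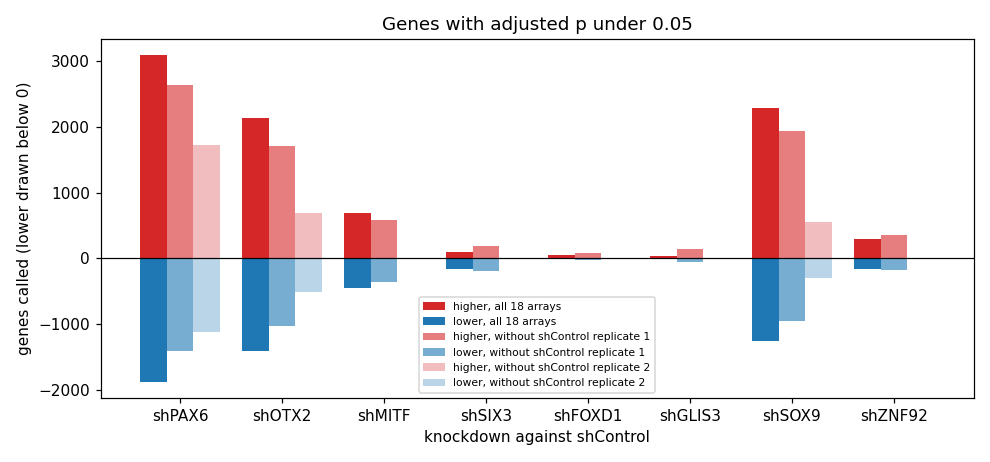
Number of genes called higher (red) and lower (blue, drawn below 0) in each knockdown against shControl (limma, adjusted p under 0.05, of 12272 genes), with all 18 arrays and, in paler bars, without either shControl array. With all arrays the counts run from 50 in shGLIS3 to 4967 in shPAX6, and without shControl replicate 2 from 0 to 2847.

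Setting each knockdown against the other 7 asks where it differs from them, with the controls left out of the contrast but not of the spread. A gene whose shared change is only stronger or weaker in 1 knockdown is called too. ELN in shPAX6 was also among the 8 largest falls of the mean. Deviations from the mean of the 8 correlated at 0.681 for shPAX6 and shOTX2 and -0.826 for shPAX6 and shFOXD1. A call here thus does not make a gene specific to 1 factor. In shPAX6 the vitamin D hydroxylase CYP24A1 (-2.28 ± 0.31, adjusted p = 0.00381), PAX6 itself (-2.08 ± 0.12, adjusted p = 1.55e-06) and ELN (-1.88 ± 0.28, adjusted p = 0.00483) fell, and the stress pseudokinase TRIB3 (1.27 ± 0.27, adjusted p = 0.00999), the RNA gene THORLNC (1.27) and the GTPase RAB39B (1.21) rose. Of 2538 genes 1656 were higher and 882 lower, or 1080 and 1186 after quantile normalization. The count was 4 without shPAX6 replicate 1, where all of these genes but PAX6 lost their calls (adjusted p = 0.0619 to 0.0999), and 1021 without shPAX6 replicate 2, where TRIB3 lost its call (0.0594). In shOTX2 the thyroid-hormone activating enzyme DIO2 (-1.12 ± 0.14, adjusted p = 0.0141), OTX2 (-1.74 ± 0.25, adjusted p = 0.0379) and ACTC1 (-1.93 ± 0.35, adjusted p = 0.0459) were lower and osteopontin (SPP1, 1.72), the arrestin ARRDC4 (1.08) and the metalloreductase STEAP1 (0.79) higher. Of 33 genes 17 were higher and 16 lower, or 18 and 45 after quantile normalization; the count was 11 with log2(value + 1) and 7 with the mean over probe sets. In shFOXD1 FOXD1 (-1.54 ± 0.20, adjusted p = 0.0216), the cysteine-forming enzyme CTH (-1.47 ± 0.25, adjusted p = 0.0446) and the immune ligand ULBP1 (-1.12) were lower and RHOBTB1 (0.85), PDGFRB (0.65) and the respiratory subunit COX7B (0.43) higher. Of 63 genes 3 were higher and 60 lower, against 2 in all after quantile normalization, 36 with no filter on level, 106 with the mean over probe sets and 113 with log2(value + 1). In shSOX9 the single called gene was SOX9 (-1.30 ± 0.12, adjusted p = 0.000524), a call lost without shSOX9 replicate 2 (0.0863).

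Counts against the other knockdowns moved with single arrays. Of 18 omissions 17 moved the shOTX2 count by over 1.5 times, 14 to fewer and 3 to more, from 0 without shOTX2 replicate 1 to 434 without shSIX3 replicate 1. For shFOXD1 16 did, 14 to fewer and 2 to more, from 0 without shGLIS3 replicate 1 to 1081 without shSIX3 replicate 2, and for shSOX9 5 did, from 0 without shSOX9 replicate 2 to 11 without shSIX3 replicate 1. Without shControl replicate 1, or without replicate 2, the count was 3 for shOTX2 and 2 for shFOXD1. All 6 genes named for shOTX2 lost their calls without either of its arrays (OTX2 at 0.187 and 0.0665). Over the 18 omissions OTX2 lost its call in 8 and the other named genes but DIO2 in 13 to 15. After quantile normalization the genes named for shFOXD1 but FOXD1 lost theirs (0.0682 to 0.0701), and FOXD1 lost its own in 4 omissions: shGLIS3 replicate 1 (0.0554) or 2 (0.0507), shSOX9 replicate 1 (0.0562) and shZNF92 replicate 2 (0.0555). The other 5 lost theirs in 12 to 16 of the 18 omissions (up to 0.556). Limma called 0 genes in shMITF, shSIX3, shGLIS3 and shZNF92, where 1035, 998, 1350 and 907 had an unadjusted p under 0.05. The targets there differed from the other knockdowns by -0.89 for MITF (adjusted p = 0.213), -1.19 for SIX3 (0.424), -0.91 for GLIS3 (0.324) and -1.14 for ZNF92 (0.662). The counts of 0 became 118 in shMITF without shMITF replicate 2, 3 in shSIX3, 4 in shGLIS3 and 2 in shZNF92 without shSIX3 replicate 2. The same lists tested against the other 7 knockdowns, a comparison chosen after seeing the data, gave 70 camera calls of 144 and 0 with an estimated correlation (lowest adjusted p = 0.384).

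The knockdowns shared much of their change against shControl, in part because they share its 2 arrays. Across genes, which are not independent replicates, fold changes of 2 knockdowns correlated at a mean r of 0.859 over 28 pairs, from 0.692 for shPAX6 and shFOXD1 to 0.948 for shPAX6 and shOTX2. Simulated unchanged knockdowns with shared controls gave 0.501 on average, and at most 0.514 in 100 sets. The mean covariance was 0.157, from 0.0845 to 0.307, against 0.0146 simulated. The simulated noise was independent between genes and of equal spread in all groups, so its r follows from the shared controls alone. In the data the median SD between controls exceeded that within knockdowns for interferon genes (1.25 against 0.390). Over all genes it was lower (0.0969 against 0.146). The simulated values thus do not bound what the controls can add. shPAX6 and shOTX2 had 1959 genes higher in both, where independent lists give 540, and 1252 lower in both against 215. shPAX6 and shSOX9 had 2027 against 576 higher and 1127 against 193 lower, and shOTX2 and shSOX9 1735 against 399 and 1023 against 145, with 0 genes in opposite directions by limma. The numbers for independent lists leave the shared controls out of account. The controls could not be split between knockdowns, with 2 arrays in all, so part of the excess may come from them, above all for interferon genes, where they differ. Mean r was 0.808 without shControl replicate 2 and 0.900 without shControl replicate 1. As deviations from the mean of the 8, pairs correlated at -0.826 to 0.682.

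The iRPE clones, made from fibroblasts, had no comparison group, so their levels are given without a test. The list genes named are among the 6 with the highest level of their list, and probe sets differ in affinity, so levels do not rank genes or lists. From the RPE, pigment and visual-cycle lists they included the anti-angiogenic SERPINF1 at 15.28, the metalloproteinase inhibitor TIMP3 at 15.17, TTR at 14.87, the water channel AQP1 at 14.59, the keratin KRT18 at 14.57, the chaperone CRYAB at 14.08, the carotenoid enzyme BCO1 at 13.51, the melanosome protein GPNMB at 14.07 and TYR at 10.73 in clone 42 and 11.27 in clone 46. Junction genes TJP1 (12.60) and CDH3 (12.54) stood beside the mesenchymal genes TGFBI (15.47), VIM (14.96) and SPARC (14.19), with the fibroblast genes PDGFRB at 11.19 and COL1A1 at 9.07. Of the factors SOX9 was at 12.53, FOXD1 at 11.40, MITF at 11.12, LHX2 at 10.80, ZNF92 at 10.44, GLIS3 at 9.55, SIX3 at 8.42, OTX2 at 8.04 and PAX6 at 7.32, which in that order lay at percentiles 92.4, 81.7, 78.3, 74.0, 68.6, 54.9, 38.1, 33.5 and 25.0 of 13908 genes. By list, the median percentile was 86.9 for phagocytosis genes, 73.5 for RPE markers, 61.2 for melanin genes, 54.1 for mesenchymal, 42.1 for visual-cycle, 39.5 for epithelial and 33.3 for fibroblast genes. Lipid synthesis (81.1), p53 (75.5), stress (71.6), Wnt, BMP and TGF-beta (68.7) and complement genes (67.0) had these median percentiles, and cell-cycle genes had a median level of 9.62. The value was 44.2 for interferon, 34.2 for inflammatory, 22.2 for photoreceptor, 20.2 for melanocyte and 14.5 for endothelial genes.

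The clones correlated at 0.985 across genes, and 392 genes differed over 2-fold, 234 higher in clone 46 and 158 in clone 42. The monoamine oxidase MAOA (3.16), FAM124B (3.12), the growth-factor homologue FGF13 (2.97), ANKS1B (2.96), the lymphocyte receptor CD5 (2.48) and KLF3-AS1 (2.43) were higher in clone 46. The chemokine receptor ACKR3 (-3.57), the adhesion molecule CADM1 (-2.68), ADIRF (-2.61), the chloride channel BEST4 (-2.33), ALPK3 (-2.29) and IFITM10 (-2.10) were lower in it. Several had a low level in 1 clone: MAOA (4.87), CD5 (5.04) and KLF3-AS1 (4.70) in clone 42, BEST4 (4.78) and IFITM10 (4.89) in clone 46. The size of those differences depends on the background and the added 16. SIX3 was at 7.67 in clone 42 and 9.17 in clone 46, and the SD of all clone differences was 0.387.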

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

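In the paragraphs here the tests of array scaling, of the control level, of left-out arrays in the ratio of counts, of knockdown depth, of MITF and of the size of changes with the ACTB covariate were chosen only after the result was seen, while the other covariate tests had their bounds written before. The size test is the third rule used for RNA quality in the number of genes called, and its bound, a share of 0.5 left, was set after the shares had been seen.

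A tested difference between knockdowns singled out 4 results: the genes that differed from the other 7 knockdowns numbered 2538 in shPAX6, 33 in shOTX2, 63 in shFOXD1 and 1 in shSOX9. That single gene was SOX9 itself. The counts were 4 without shPAX6 replicate 1 for shPAX6, 0 without shOTX2 replicate 1 for shOTX2, 0 without shGLIS3 replicate 1 for shFOXD1 and 0 without shSOX9 replicate 2 for shSOX9. What made these knockdowns differ was not tested.

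Interferon genes were higher in all 8 knockdowns. Camera called the list up in 8 of 8 knockdowns after quantile normalization, but in 0 with an estimated correlation (lowest adjusted p over all lists 0.233). This cannot decide on array scaling, because the shift is taken against other genes of the same arrays. Scaling a whole array moves both alike. A low level in the control arrays may be part of the rise. The lowest knockdown array lay 0.73 above the higher control in the interferon mean. The controls themselves lay at 1.02 and -1.02, so more controls would be needed. Depth of the knockdown stays open too, since the hairpin with the deeper loss tended to have the lower interferon mean, the direction against this explanation, but chance was not excluded (r = 0.483, exact permutation p = 0.224, adjusted p = 0.359 over 8 relations; rho = 0.619, p = 0.115; r = 0.587 without the 2 farthest factors). A response to the hairpin or virus dose, which the design does not separate from the loss of a factor, was not tested.

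RPE marker genes were lower in all 8 knockdowns, measured against the other genes. Their mean lay at -1.09 and -0.44 in shSIX3, -0.76 and -0.55 in shMITF, -0.37 and -0.43 in shGLIS3 and -0.39 and -0.59 in shZNF92. Spike-in RNA lay at -0.94, -0.79, -0.41 and -0.54 there, in that order. In these knockdowns a fall in level thus rests on the scaling as deposited. With the interferon mean of each array as a covariate the list was still called down in 7 of 8 (shifts -1.18 to -0.28), and with the ACTB 3 prime to 5 prime difference in 8 of 8 (-1.41 to -0.49). A downward shift thus stayed in each knockdown with either covariate. Both tests rest on the preset correlation, and both slopes on differences within groups. They therefore do not decide on the interferon level or RNA quality as a cause. With an estimated correlation camera called 0 lists with either covariate (lowest adjusted p = 0.344 for the interferon mean and 0.229 for ACTB). With the interferon covariate limma called 0 single genes in any knockdown. It had 8 residual degrees of freedom and a covariate set mostly by the gap between the controls, so the interferon test is weak evidence. Lower MITF in each array cannot be told apart from a common change, although it tracked the melanin mean over 14 arrays of other knockdowns (r = 0.784, permutation p = 0.00025, adjusted p = 0.000667 over 8 relations; rho = 0.798, p = 0.00105; r = 0.675 without the 2 farthest), because 7.14% of 12246 genes tracked the melanin mean as closely in the same direction and 11.99% in either. That comparison with other genes was added after the correlation had been seen. The permutation took the 14 arrays as separate, though they are 2 per knockdown. Over 7 group means r was 0.823 (exact permutation p = 0.0177).

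Many more genes were called in shPAX6, shOTX2 and shSOX9 than in the other knockdowns, 10.3 times as many on average (5.46 without shSIX3 replicate 2 to 327 without shControl replicate 2). After quantile normalization the ratio was 9.99, and each of the 3 counts stayed above the other 5. That step gives all arrays the same distribution of values, so it cannot test a shift of most genes in a group. Spike-in RNA lay -0.21 from shControl in shPAX6, -0.39 in shOTX2 and -0.64 in shSOX9. Among the other 5 it ran from -0.94 in shSIX3 to -0.16 in shFOXD1. Counts relative to spike-in RNA were not computed, so array scaling stays open. For RNA quality the ratio with the ACTB covariate was 4.85, past the bound of 4 written before, but it ran from 0.759 without shPAX6 replicate 1 to 326 without shMITF replicate 1, and without shControl replicate 2 limma called 0 genes in each knockdown (350 to 2099 at an unadjusted p under 0.05), so counts do not decide. The calls ended, from 3548 to 2 in shSOX9, mainly because the SE widened. Over the genes called the median change went from 0.65 to 0.61 in shPAX6, 0.64 to 0.61 in shOTX2 and 0.61 to 0.56 in shSOX9. The median SE went from 0.15 to 0.22, 0.16 to 0.23 and 0.15 to 0.24. A share of at least 0.919 was left (0.788 with arrays left out), so changes within these 3 knockdowns kept most of their size with this covariate. That does not say why the 3 exceed the other 5, so RNA quality stays open for the ratio. The ACTB slope also rests on differences within groups. The widest was that of shMITF (0.84 and 1.36), whose 2 arrays carry different hairpins. Depth of the knockdown stays open, with more genes called at the deeper loss but not beyond chance (r = -0.402 over 8 knockdowns between target change and genes called, exact permutation p = 0.338, adjusted p = 0.386 over 8 relations; rho = -0.500, p = 0.216; r = 0.0935 without the 2 farthest), and a larger role of these factors in RPE cells remains an untested biological candidate.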

How the results depend on the processing

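The leave-one-out of the similarity, the fry test and the covariates were chosen after seeing the data. Signal near background limits what can be seen in dim genes, and with 2 arrays a lone array is assumed to vary like the other groups. Leaving out 1 array gave these target changes, lowest to highest: PAX6 -1.92 to -1.74, OTX2 -2.77 to -2.08, MITF -1.91 to -1.51, SIX3 -2.36 to -1.46, FOXD1 -2.22 to -0.98, GLIS3 -1.02 to -0.46, SOX9 -1.48 to -1.06 and ZNF92 -2.05 to -0.90. With an array of the 2 compared groups left out, genes called against shControl ran from 2847 to 4123 in shPAX6, 1212 to 2872 in shOTX2, 16 to 941 in shMITF, 0 to 1470 in shSIX3, 0 to 106 in shFOXD1, 0 to 193 in shGLIS3, 846 to 2887 in shSOX9, 0 to 537 in shZNF92 and, over all arrays, 124 to 3695 in the mean. Where limma called 0, all arrays gave 1287 (shFOXD1) to 2781 (shZNF92) at an unadjusted p under 0.05. The sum of calls against the other 7 knockdowns ran from 12 to 3962, with 4 to 3217 in shPAX6, 0 to 434 in shOTX2, 0 to 118 in shMITF, 0 to 3 in shSIX3, 0 to 1081 in shFOXD1, 0 to 4 in shGLIS3, 0 to 11 in shSOX9 and 0 to 2 in shZNF92; where limma called 0 with all arrays, 907 to 1350 had an unadjusted p under 0.05. Leaving out 1 array took factor calls in other knockdowns from 0 to 15, list calls from 66 to 74 and mean r from 0.808 to 0.900. The cell-cycle list in shSIX3 reversed to 0.0912 without shSIX3 replicate 1. Fitting only 4 arrays gave 655 genes in shMITF, 0 in shSIX3 and shFOXD1, 78 in shGLIS3 and 697 in shZNF92. The shGLIS3 count of 50 became 84 with quantile normalization or log2(value + 1), 92 with no filter, 96 with the mean over probe sets and 0 without the trend. The mean over probe sets also took GLIS3 to -0.34 (adjusted p = 0.149). Factor calls in other knockdowns rose to 11 with no filter and 11 with the array number as a block, numbers that do not pair arrays: same-numbered arrays correlated at -0.363 to 0.284 in their deviations. Against the other 7 knockdowns the shOTX2 count of 33 became 63 with quantile normalization, 11 with log2(value + 1) and 7 with the mean over probe sets. The shFOXD1 count of 63 became 2 with quantile normalization or the block, 113 with log2(value + 1), 36 with no filter and 106 with the mean over probe sets, and the shGLIS3 count of 0 became 1 with quantile normalization or the mean over probe sets. With the ACTB covariate the counts against shControl were 1674 in shPAX6, 632 in shOTX2, 2 in shSOX9, 341 in the mean and 0 in shSIX3, shFOXD1, shGLIS3 and shZNF92, where limma gave 828 to 1934 at an unadjusted p under 0.05. With the interferon covariate limma called 0 in the mean and all 8 knockdowns (265 to 2033 at an unadjusted p under 0.05). With an estimated correlation camera called 0 lists, with 19 at an unadjusted p under 0.05, and fry 48. The cause was not tested for any of these. In the counts that follow, the other settings are quantile normalization, log2(value + 1), no filter, no trend, the mean over probe sets and the block. The covariates, the fit of 4 arrays, fry and the estimated correlation are not counted there. The estimated correlation alone ended all 68 list calls, and with the interferon covariate limma called 0 genes. Of the named genes, 621 omissions ended a call, 47 added 1 and 2574 left it as it was; the other settings ended 93, added 39 and left 3996. For lists the omissions ended 16 and added 21, and the other settings ended 4 and added 13.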

Other observations

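The relations here, and the spike-in values, were tests chosen only after the results were seen. Permutations over 14, 16 or 18 arrays took the arrays as separate, though they are 2 per group. For OTX2 no value over group means was computed.

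Spike-in RNA (28 ERCC probe sets) ran from 0.61 above the 18-array median in shControl replicate 1 to -0.74 in shSIX3 replicate 1, and it followed the lys spike-ins closely (r = 0.996, rho = 0.986, permutation p = 1e-05, the smallest possible, adjusted p = 8e-05; r = 0.994 without the 2 farthest). Relative to the ERCC probe sets the targets changed by -1.62 (PAX6), -2.03 (OTX2), -0.92 (MITF), -0.97 (SIX3), -1.44 (FOXD1), -0.32 (GLIS3), -0.63 (SOX9) and -0.94 (ZNF92). The spike-in change against shControl ran from -0.94 in shSIX3 to -0.16 in shFOXD1 and bears on every gene of a group. Falls of single genes near that size, and the numbers higher and lower, thus rest on the scaling as deposited. The ACTB 3 prime to 5 prime difference was 0.76 and 0.99 in the controls and 0.84 to 1.56 in the knockdowns. That of GAPDH was 0.18 and 0.19 in the controls and 0.10 to 0.41 in the knockdowns.

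The interferon mean and the RPE marker mean showed no clear relation over the 16 knockdown arrays (r = -0.0796, permutation p = 0.774, adjusted p = 0.774 over 8 relations; rho = -0.238, p = 0.372; r = -0.300 without the 2 farthest). OTX2 tracked the RPE marker mean, taken without the 9 factors, over the 14 arrays of other knockdowns (r = 0.876, permutation p = 7e-05, adjusted p = 0.00028; rho = 0.829, p = 0.00054; r = 0.784 without the 2 farthest), as 2.83% of 12234 genes did as closely in the same direction and 7.39% in either. MITF and the melanin mean over 7 group means gave r = 0.823 (exact permutation p = 0.0177, adjusted p = 0.0353; rho = 0.821, p = 0.0341; r = 0.924 without the 2 farthest). Hairpin differences in the target and in the RPE marker mean gave r = 0.429 over 8 factors (exact permutation p = 0.296, adjusted p = 0.386; rho = 0.429, p = 0.299; r = 0.634 without the 2 farthest).

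The first component of the 18 arrays held 53.1% of the variance and the next 11.8%, and the 2 arrays of a group correlated at 0.980 to 0.992 across genes.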
